A study of Mus musculus with 8 samples.

How the data were processed

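Macrophages were grown from the bone marrow of female mice that were wild type (WT) or carried a knockout of NF-κB-inducing kinase (NIK KO), 2 mice of each genotype. Per the labels' protocols, marrow cells spent 7 days in medium holding 30% supernatant of L929 cells, a fibroblast line used as a source of the macrophage growth factor M-CSF, and were replated in 5%. Cells of each mouse were then kept for 6 hours with PBS or with 20 ng/mL of interleukin 4 (IL-4). This gave 8 RNA libraries in 4 groups of 2, and the same 4 mice stand behind both treatments.

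The labels tie the libraries to 2 tables of per-gene results, 1 for each treatment, each comparing the genotypes over 4 libraries. Per the submitters' processing notes, Salmon 1.4.0 and DESeq2 1.32.0 were used with genome build GRCm39, and the role of each, the annotation and any filter are not given in the sources used here. Per the file headers, the authors deposited a base mean for each gene, a signal that averages counts divided by size factors over the libraries of a table. Per the file headers, the authors also deposited the log2 fold change and its standard error on the log2 scale. The deposited Wald statistic is a score, and in both tables it equals the log2 fold change divided by its standard error to within rounding, so the fold changes were not shrunken after the test. The p-value and the adjusted p-value were deposited by the authors as DESeq2 gives them, and Benjamini-Hochberg adjustment of the deposited p-values gave back the deposited adjusted values to within 3.20e-05. With IL-4, 551 genes have no adjusted p, all of base mean 3.49 or lower, and they were left as such.

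The direction of the fold change, NIK KO over WT, was taken from the name of the IL-4 table and applied to both tables. The gene of NIK, Map3k14, is higher on the side taken as NIK KO in both tables, so the text writes of libraries labelled NIK KO. Both tables give 1 value per gene and comparison. The depth of each library is therefore unknown here, and no interval per library is given. Base means summed to 1.42e+07 over all genes with PBS and 1.66e+07 with IL-4. The standard error sets the precision: among genes of base mean 100 or more its median was 0.30 on the log2 scale with PBS (9266 genes) and 0.22 with IL-4 (9513 genes). With 2 mice on each side, the spread of a gene rests in part on the authors' fit across all genes.

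A gene was called at a deposited adjusted p under 0.05. A change in the NIK KO effect between treatments was tested as the difference of the 2 log2 fold changes over the root of their summed squared standard errors, against the normal distribution, two-sided, with Benjamini-Hochberg adjustment over the 13384 genes in both tables. This z test treats the errors as independent although the mice are shared. Gene lists were tested with cameraPR of limma 3.58.1 in R 4.3.3 on the deposited Wald statistic, two-sided, with a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over the 38 lists of a table with at least 3 measured members. A correlation estimated from the data needs values per library, so presets of 0, 0.05, 0.1 and 0.2 were tried in its place. The set test takes genes as its units, so its p-values do not measure the spread between mice. Lists added after the data were seen, those of embryonic and placental genes and the sets raised or lowered by IL-4, were adjusted apart, among themselves. Calls within a list were also counted with p-values adjusted over the list alone. The 30 pathway lists and 9 lists of cell markers, the thresholds, the designs and the rule for naming genes were set before the data were examined.

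Mean normalized counts per group were recovered from the base mean and the fold change, since both groups of a table are of equal size. Levels with PBS and with IL-4 come from tables normalized separately and carry no test. Sharing of sequence was measured as the percent of the 31-base words in a gene's longest transcript that also occur in transcripts of another gene. Transcript length and GC content were those of a gene's longest transcript. All were taken from the GENCODE M21 transcripts of GRCm38. That reference is not the authors' build, so it was used for sequence sharing, transcript length, GC content, the chromosome of a gene and nearness to Map3k14 (within 10 Mb), and no coordinates are printed. Gene names are those in the files. Other calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6, and figures were drawn with matplotlib 3.10.9. The steps were tested on simulated fold changes with the deposited standard errors. Of 100 genes changed by 1 on the log2 scale, 39 were called with PBS, 71 with IL-4 and 29 in the difference between treatments. Of 100 genes changed by 2, 97, 98 and 89 were called. False calls among unchanged genes numbered 8 with PBS, 4 with IL-4 and 8 in the difference. Changed genes were drawn from those of base mean 100 or more (with IL-4 for the difference), so these shares do not cover lower genes. The simulated noise was as wide as the deposited standard errors, while the real statistics spread less (robust SD 0.641 with PBS and 0.810 with IL-4). The counts therefore hold for that wider noise only. Of the 38 lists, 3 were shifted, and cameraPR called these 3 and no others. The simulated genes were independent of each other, so this does not tell of false calls among genes that move together.

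Named genes are Map3k14, Nfkb2, Relb, Arg1, Retnla, Chil3 and Mrc1 whatever their test, and the 8 largest rises and falls among called genes of base mean 50 or more whose symbol is not that of a predicted gene, clone or pseudogene. They also take in up to 4 members of each list that passed, by adjusted p, the 2 members of highest base mean of marker lists, and the 5 genes of smallest adjusted p in each direction of the difference. Adjusted p-values were tied within most lists, so members were taken in the direction of the set test and then by unadjusted p. Predicted genes and pseudogenes, Pappa2, Lamb3, Col5a1, the embryonic and placental genes, Cd5l, Fcrls, mt-Nd4l and genes named for their level alone were chosen after their values were seen. Alternatives were other thresholds and minimum levels, a t distribution, an empirical null fitted to the statistics, ranks or fold changes in the set test, other inter-gene correlations, removal of genes near Map3k14 or of genes with over 50% shared words, and subtraction of smooth trends (lowess, fraction 0.3) on length, GC content or base mean. Removal of single libraries, a block by mouse and another normalization were planned and were not run, since they need values per library.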

Results

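RNA sequencing compared bone-marrow-derived macrophages of WT mice with those of mice knocked out for NIK, the kinase that starts noncanonical NF-κB signalling by driving the processing of the NF-κB2 precursor. Macrophages of 2 WT and 2 NIK KO mice were kept with PBS or with 20 ng/mL IL-4 for 6 hours, giving 8 libraries in 4 groups of 2. IL-4 is the cytokine that turns macrophages to the alternatively activated (M2) state. The series title names mitochondrial respiration, differentiation and inflammatory state as the subject, and the comparison of genotypes within each treatment addresses it at the level of RNA. The authors' deposited tables cover 13676 genes with PBS and 14193 with IL-4, and the depth of each library is unknown. Fold changes are given on the log2 scale with their standard error, 2 mice against 2.

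Map3k14, the gene of NIK (ENSMUSG00000020941, chromosome 11), was higher in the libraries labelled NIK KO under both treatments, the reverse of what the label of a knockout would give. With IL-4 it rose 1.99-fold in the authors' deposited table (0.99 ± 0.22, mean normalized count 418 in WT and 832 in NIK KO, adjusted p = 0.00782 by the authors' DESeq2 Wald test with Benjamini-Hochberg adjustment). With PBS the authors' deposited table gives 2.12-fold (1.09 ± 0.28, 425 in WT and 902 in NIK KO), which did not pass (DESeq2 p = 1.08e-04, adjusted p = 0.176). Which part of the gene was removed is not given in the sources used here, and reads outside a removed part would still count. A reversed direction in the tables is not excluded, and it would turn the sign of every change and exchange the WT and NIK KO means given here. Nfkb2 and Relb, which encode the subunits of the noncanonical pathway, were not called. In the authors' deposited tables Nfkb2 was at -0.51 ± 0.34 with PBS and -0.13 ± 0.25 with IL-4, and Relb at -0.32 ± 0.34 and -0.11 ± 0.27. The noncanonical NF-κB list did not pass (cameraPR adjusted p = 0.568 with PBS over 18 genes and 0.280 with IL-4 over 19). Map3k14 was its call over all genes with IL-4 and, adjusted over the list alone, its 1 call in each table.

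With PBS, interferon-stimulated genes and the genes of antigen presentation stood higher as groups in the libraries labelled NIK KO, and mitotic genes stood lower, while few single genes passed. The interferon-stimulated genes rose together, with 43 of 44 measured members higher and a median of 0.28 (cameraPR adjusted p = 1.61e-14). Among them, the authors' deposited table gives Iigp1, an interferon-induced GTPase, at 1.21 ± 0.42 and Rsad2, the antiviral enzyme viperin, at 0.79 ± 0.29. Ifit3b was at 0.83 ± 0.30 and Cmpk2 at 0.66 ± 0.29 in the authors' deposited table. The genes of MHC class II presentation rose, with 10 of 11 higher and a median of 0.58 (cameraPR adjusted p = 1.52e-07). In the authors' deposited table Cd74, the invariant chain, was at 0.77 ± 0.31 (5980 against 10227 mean normalized counts) and Ciita, the transactivator of the class II genes, at 0.73 ± 0.32. H2-Ab1 was at 0.72 ± 0.32 and H2-Eb1 at 0.58 ± 0.35 in the authors' deposited table.

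The MHC class I list also rose with PBS, 14 of 16 higher with a median of 0.21 (cameraPR adjusted p = 0.00162). Its members Tapbp, the peptide-loading chaperone tapasin, and Tap1, a peptide transporter, were at 0.40 ± 0.23 and 0.35 ± 0.24 in the authors' deposited table, and H2-T22 and H2-Q6 at 0.39 ± 0.28 and 0.36 ± 0.31. The G2/M and mitosis list fell in the libraries labelled NIK KO, with 27 of 30 lower and a median of -0.24 (cameraPR adjusted p = 1.07e-05). The authors' deposited table puts Hmmr, a spindle protein, at -0.68 ± 0.37, Cdca3 at -0.45 ± 0.28, and the kinetochore genes Nuf2 and Ndc80 at -0.41 ± 0.32 and -0.35 ± 0.28. DNA replication genes did not pass (median -0.03, cameraPR adjusted p = 0.663). In the 4 lists that passed, DESeq2 called 0 members, and 0 passed adjusted over the list alone. At an unadjusted p under 0.05 stood 5 interferon-stimulated genes, 3 MHC class II genes and 0 of the other lists. The other 34 lists did not pass (cameraPR adjusted p from 0.168 to 0.975), complex I and complexes II to V of the respiratory chain among them (0.218 and 0.676). The interferon and MHC class II calls held at every inter-gene correlation tried, up to 0.2 (adjusted p = 0.0316 and 0.0180), and were lost when fold changes replaced the statistic (0.177 and 0.599), as were the MHC class I and mitosis calls (0.986 and 0.785). Fold changes are not divided by their error, so genes listed near 0 widen their spread, and a loss in that setting says little. The MHC class I and mitosis lists had adjusted p = 0.102 and 0.0580 at a correlation of 0.1, and MHC class I 0.0507 after a trend on base mean was subtracted. These p-values take genes as units and do not measure the spread between mice. A difference between these mice that owes nothing to genotype could therefore also shift the lists.

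Of 13676 genes with PBS, 5 were called, 2 higher and 3 lower in the libraries labelled NIK KO, and 4 of them share most of their sequence with another gene. Gdf3, a secreted factor of the TGF-β family (ENSMUSG00000030117, chromosome 6), was the exception. It fell to 0.372 of the WT level in the authors' deposited table (-1.43 ± 0.32, 749 against 279 mean normalized counts, DESeq2 adjusted p = 0.0224). Kpna2, an importin that carries proteins into the nucleus (ENSMUSG00000018362, chromosome 11), fell by 4.58 ± 0.28 in the authors' deposited table, from 2140 to 89.7 (DESeq2 adjusted p = 3.48e-56). Gm10184 on chromosome 17, of which 95.8% of the 31-base words are in Kpna2, stood at 0.172 in WT and 2525 in NIK KO (DESeq2 adjusted p = 2.61e-17, authors' deposited table). The sum of the pair was 2140 in WT and 2614 in NIK KO, a log2 ratio of 0.29. The pseudogenes Pgam1-ps2, lower in NIK KO, and Rpl10a-ps1, higher, are each listed near 0 in 1 genotype (DESeq2 adjusted p = 0.00108 and 0.00152 in the authors' deposited table). They have 100% of their words in Pgam1 and Rpl10a. Genes with over 50% shared words made up 4 of 5 called genes and 8.37% of genes not called. Shared words were measured because the called genes had been seen to be copies, and Kpna2 and Gm10184 count as 2 calls, so these shares carry no test. Without such genes 0 passed on the DESeq2 p-values. With a t distribution of 2 degrees of freedom 0 passed, an outcome fixed beforehand, since not even the largest statistic could pass under its wide tails. An unadjusted DESeq2 p under 0.05 was found for 169 of 13676 genes in the authors' deposited table. That is 1.24% where chance alone gives 5%.

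**Figure D1:**
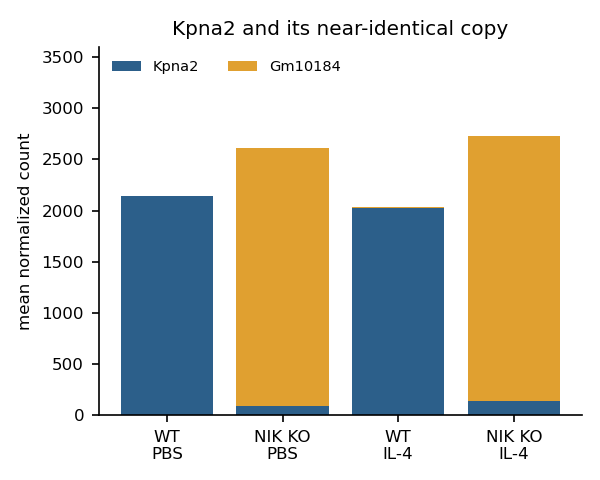
Mean normalized counts of Kpna2 (blue) and of its near-identical copy Gm10184 (orange), stacked, in the 4 groups of 2 mice each, recovered from the base means and fold changes of the authors' deposited tables (no error bars, since no values per library were used). Kpna2 holds nearly all of the pair's counts in WT (2140 with PBS) and Gm10184 in libraries labelled NIK KO (2525 with PBS), while the sum of the pair differs by 0.29 on the log2 scale with PBS and 0.43 with IL-4.

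With IL-4, the respiratory chain, the ribosome and mitosis stood lower as gene groups in the libraries labelled NIK KO, and the interferon, antigen presentation, and LXR and lipid handling groups stood higher. In the same libraries markers of fibroblasts and erythroid cells were lower, with medians of -0.98 and -0.96, and short transcripts were lower in general. The median was -0.13 for the fifth of genes with the shortest transcripts and 0.11 for the fifth with the longest. Both lists of nuclear-encoded respiratory chain genes fell. Of 36 complex I genes 33 were lower (median -0.23, cameraPR adjusted p = 6.40e-07), and of 42 genes of complexes II to V 39 were lower (median -0.21, adjusted p = 1.79e-08). In the authors' deposited table the complex I subunits Ndufb10, Ndufb3, Ndufb6 and Ndufs4 were at -0.39 ± 0.19, -0.41 ± 0.22, -0.40 ± 0.22 and -0.38 ± 0.22. The cytochrome c oxidase subunits Cox6c and Cox7a2 were at -0.42 ± 0.18 and -0.40 ± 0.20, and the ATP synthase subunits Atp5e and Atp5l at -0.49 ± 0.22 and -0.38 ± 0.18 (authors' deposited table). Of these lists DESeq2 called 0 members, and 0 passed adjusted over the list alone, while 1 complex I gene and 4 of complexes II to V had an unadjusted p under 0.05, all lower. Cytosolic ribosomal protein genes fell together, 49 of 50 lower with a median of -0.17 (cameraPR adjusted p = 1.79e-08). Rpl13a was at -0.36 ± 0.17, Rplp1 at -0.31 ± 0.17 and Rps24 at -0.28 ± 0.16 in the authors' deposited table. DESeq2 called 0 of the 50, 0 passed adjusted over the list alone, and 1 had an unadjusted p under 0.05. The ribosomal and both respiratory chain calls were lost at an inter-gene correlation of 0.2 (adjusted p = 0.157 each) and on fold changes (0.780 each). Subtraction of the trend on transcript length moved the mean statistic of the ribosomal list from -0.955 to -0.642, and the list still passed (cameraPR adjusted p = 1.18e-04).

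Mitochondrially encoded genes fell as a list with IL-4 in the libraries labelled NIK KO, 12 of 13 lower with a median of -0.15 (cameraPR adjusted p = 0.00244). The call was lost at an inter-gene correlation of 0.1 (adjusted p = 0.0643) and after the trend on transcript length was subtracted (0.0616). In the authors' deposited table mt-Co2, a cytochrome c oxidase subunit, fell to 0.530 of the WT level (-0.91 ± 0.18, DESeq2 adjusted p = 9.48e-04), from 16006 to 8491 mean normalized counts. All of its 31-base words (100%) are also in other genes, above all Gm28661, and the sum of that pair had a log2 ratio of -0.31. Adjusted over the list alone, 2 genes were called lower and 1 higher: mt-Co2, mt-Co3 at -0.67 ± 0.23 and mt-Nd4l at 0.86 ± 0.24 in the authors' deposited table, the last pair with 99.9% and 98.9% shared words. The other members lay between -0.51 ± 0.58 (mt-Nd3) and 0.00 ± 0.15 (mt-Co1) in the authors' deposited table. Antioxidant genes fell, 20 of 26 lower with a median of -0.13 (cameraPR adjusted p = 0.0157). That call was lost at an inter-gene correlation of 0.05 (adjusted p = 0.111) and after subtraction of the length trend (0.0616). The authors' deposited table has Sod1, superoxide dismutase, at -0.29 ± 0.17, Nqo1 at -0.32 ± 0.20 and Prdx1 at -0.25 ± 0.19. The mitosis list fell with IL-4 too, 28 of 30 lower with a median of -0.17 (cameraPR adjusted p = 2.67e-05). Ube2c, which acts in the degradation of cyclins, was at -0.42 ± 0.21, the cyclin gene Ccnb2 at -0.40 ± 0.20 and Cdk1 at -0.38 ± 0.23 in the authors' deposited table. DESeq2 called 0 members of the antioxidant and mitosis lists, 0 passed adjusted over the list alone, and 0 and 1 had an unadjusted p under 0.05. The mitosis call was lost at an inter-gene correlation of 0.2 (adjusted p = 0.215) and on fold changes (0.780).

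On the higher side with IL-4, the interferon-stimulated genes rose in the libraries labelled NIK KO, 39 of 44 higher with a median of 0.19 (cameraPR adjusted p = 9.14e-08). Iigp1 was at 1.22 ± 0.35, Rsad2 at 0.61 ± 0.25, Slfn5 at 0.36 ± 0.16 and Ifit2 at 0.38 ± 0.21 in the authors' deposited table. Adjusted over the list alone 1 member passed, and DESeq2 called 0 over all genes, with 3 at an unadjusted p under 0.05. MHC class II genes rose, 8 of 11 higher with a median of 0.48 (cameraPR adjusted p = 8.02e-06). Ciita was at 0.72 ± 0.19, H2-Ab1 at 0.59 ± 0.24, Cd74 at 0.53 ± 0.20 and H2-Aa at 0.53 ± 0.24 in the authors' deposited table. Adjusted over the list alone 1 member passed, and DESeq2 called 0 over all genes, with 5 at an unadjusted p under 0.05. MHC class I genes rose, 14 of 16 higher with a median of 0.13 (cameraPR adjusted p = 0.00244), with Erap1, a peptidase that trims class I peptides, at 0.45 ± 0.18 in the authors' deposited table. LXR targets and lipid handling genes rose, 13 of 17 higher with a median of 0.18 (cameraPR adjusted p = 0.00244). The cholesterol exporters Abca1 and Abcg1 were at 0.54 ± 0.19 and 0.46 ± 0.18 in the authors' deposited table. The MHC class I and lipid handling lists each had an adjusted p of 0.0764 at an inter-gene correlation of 0.1. The interferon and MHC class II calls were lost at 0.2 (adjusted p = 0.157 and 0.118) and on fold changes (0.310 and 0.772).

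A further 3 lists rose by less with IL-4 in the libraries labelled NIK KO and were lost at an inter-gene correlation of 0.05. Cholesterol synthesis rose by a median of 0.12, 19 of 22 higher (cameraPR adjusted p = 0.0114, then 0.0798), with Lss, lanosterol synthase, at 0.51 ± 0.24 in the authors' deposited table. The unfolded protein response rose by 0.13, 17 of 20 higher (cameraPR adjusted p = 0.0257, then 0.116), with the chaperone gene Hyou1 at 0.33 ± 0.20 in the authors' deposited table. The macrophage and monocyte identity list rose by 0.07, 15 of 23 higher (cameraPR adjusted p = 0.0343, then 0.151). Adgre1, which encodes F4/80, was at 0.54 ± 0.18, the chemokine receptor Ccr2 at 0.66 ± 0.24, C5ar1 at 0.38 ± 0.17 and Csf1r, the M-CSF receptor, at 0.27 ± 0.15 in the authors' deposited table. The unfolded protein response and identity calls were also lost after a trend on base mean was subtracted (adjusted p = 0.180 and 0.115), and the identity call on ranks (0.182). DESeq2 called 0 members of the MHC class I, lipid handling, cholesterol, unfolded protein response and identity lists, and 0 passed adjusted over the list alone. At an unadjusted p under 0.05 stood 1, 2, 1, 0 and 3 members, all higher.

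**Figure D2:**
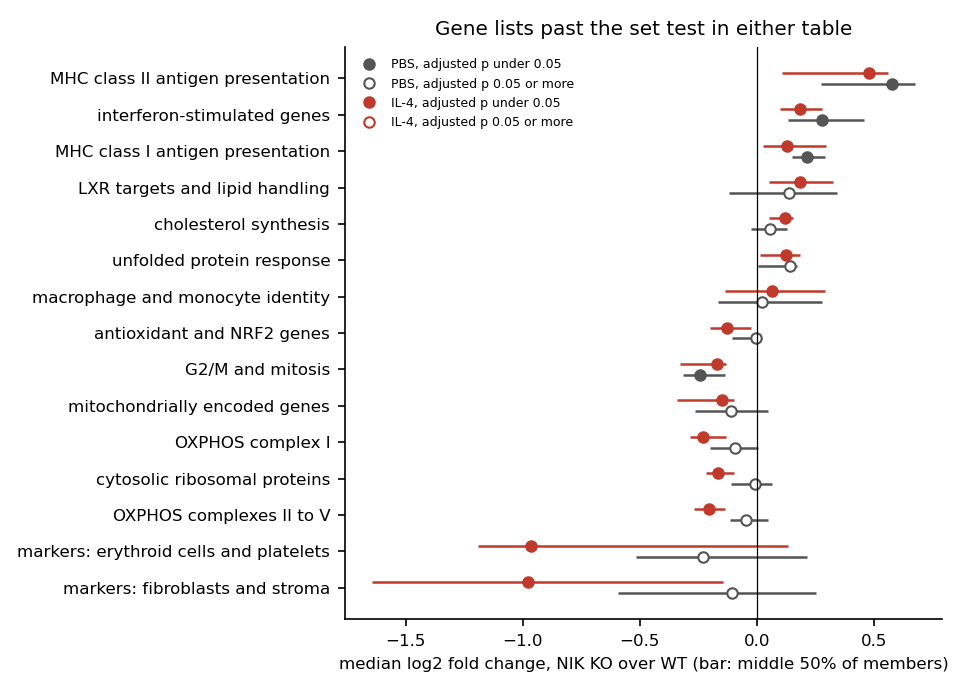
Median log2 fold change, NIK KO over WT, of each gene list that passed the set test in at least 1 table, for PBS (grey) and IL-4 (red), with bars over the middle 50% of members. Filled points passed at a cameraPR adjusted p under 0.05: MHC class II lies highest (0.58 with PBS, 0.48 with IL-4) and the fibroblast markers lowest (-0.98 with IL-4).

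The other 23 lists did not pass with IL-4. Nearest was the immediate early and heat shock list (cameraPR adjusted p = 0.0842), followed by phagocytosis receptors (0.156), fatty acid oxidation (0.247), chemokines, the TCA cycle and noncanonical NF-κB (0.280 each) and lysosome genes (0.327). After a trend on base mean was subtracted, a setting chosen after the data were seen, the immediate early list and the TCA cycle passed as lower (cameraPR adjusted p = 0.0231 and 0.0464). The IL-4 response list had a cameraPR adjusted p of 0.515, the ATF4 response 0.555 and hypoxia targets 0.588. Mitochondrial biogenesis, the pentose phosphate pathway, DNA replication and osteoclast genes stood at 0.929, glycolysis and canonical NF-κB at 0.934, and inflammatory cytokine genes at 0.943. The median, the mean and the test statistic differed in sign only for lists that did not pass. With IL-4 these were canonical NF-κB, IL-4 response, glycolysis, osteoclast and neutrophil genes. With PBS they were mitochondrial biogenesis, glycolysis, fatty acid oxidation, phagocytosis, macrophage identity, immediate early genes and the markers of B cells, T cells and progenitors.

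Of 14193 genes with IL-4, 17 were called, 7 higher and 10 lower in the libraries labelled NIK KO. Besides Map3k14, Myo9a, an unconventional myosin, rose 1.87-fold in the authors' deposited table (0.90 ± 0.22, DESeq2 adjusted p = 0.0286). Gdf3 fell to 0.340 of the WT level (-1.56 ± 0.31, DESeq2 adjusted p = 0.00120 in the authors' deposited table). Afp, the fetal serum protein alpha-fetoprotein, fell to 0.420 (-1.25 ± 0.28, adjusted p = 0.00923) and Col3a1, a fibrillar collagen of stromal cells, to 0.197 (-2.34 ± 0.53, adjusted p = 0.0107), by DESeq2 in the authors' deposited table. Kpna2 fell by 3.93 ± 0.25 in the authors' deposited table, from 2027 to 133, while Gm10184 went from 7.50 to 2599. Gm4951, which shares 10.4% of its words with the GTPase gene Iigp1, rose in the authors' deposited table (1.23 ± 0.26, DESeq2 adjusted p = 0.00366). Pappa2, a protease of the placenta, and Col5a1, a collagen, fell (-3.46 ± 0.75 and -3.72 ± 0.92), and Lamb3, a laminin chain, rose from 1.42 to 30.0 mean normalized counts in the authors' deposited table. The remaining calls, Gm10146, Gm28048, Gm45140, Gm8325 and Rpl14-ps1, have between 80.9% and 100% of their words in other genes. In all, 8 of the 17 calls had over 50% against 8.16% of genes not called, again without a test. Without such genes 6 passed: Map3k14, Gm4951, Gdf3, Pappa2, Afp and Col3a1. With a t distribution of 2 degrees of freedom on the DESeq2 statistics 0 passed, against 418 genes at an unadjusted p under 0.05 in the authors' deposited table, 2.95% where chance gives 5%.

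Markers of other cells differed with the genotype label under IL-4. The fibroblast and stroma markers fell, 12 of 15 lower with a median of -0.98 (cameraPR adjusted p = 1.36e-05). In the authors' deposited table Sparc was at -1.08 ± 0.33, Col1a2 at -1.52 ± 0.49 and Col1a1 at -1.51 ± 0.52, beside Col3a1, the 1 call over all genes, with 4 calls adjusted over the list alone. Kitl, the member of highest level, was at 0.60 ± 0.28 (authors' deposited table). Erythroid and platelet markers fell with a median of -0.96 (cameraPR adjusted p = 0.00244, 0.0784 on ranks), 5 of 9 lower and 1 called adjusted over the list alone. The globin genes Hbb-bt, Hba-a1, Hbb-bs and Hba-a2 were at -2.15 ± 0.75, -1.19 ± 0.50, -1.03 ± 0.49 and -0.96 ± 0.48 in the authors' deposited table, while Vwf, the most abundant member, was at 0.03 ± 0.19. The fibroblast and erythroid calls were lost at an inter-gene correlation of 0.2 (adjusted p = 0.157 each), and on fold changes the erythroid call was lost (0.310). With PBS neither list passed (cameraPR adjusted p = 0.663 for both). Lists of embryonic and placental genes were written after Afp, Pappa2 and a few others had been seen, and leave those out. Of their 63 measured members 58 were lower with IL-4 (median -1.27), against 23 of 48 with PBS (median 0.02). The 40 placental members came to 115 CPM in WT and 47.5 CPM in NIK KO with IL-4, and the 31 measured with PBS to 27.2 and 26.5 CPM. Embryonic and fetal erythroid members came to 35.5 and 22.9 CPM with IL-4 and 18.6 and 19.7 with PBS. Yolk sac and fetal liver members went the other way in sum, 156 and 164 CPM with IL-4 and 153 and 177 with PBS. Trf, which holds most of that sum, was at 0.18 with IL-4 in the authors' deposited table, and 12 of the 14 members were lower. Markers of dendritic cells, neutrophils, B cells, T and NK cells, mast cells and progenitors did not pass with IL-4 (cameraPR adjusted p = 0.433, 0.929, 0.280, 0.929, 0.299 and 0.299). The Y-linked genes Ddx3y and Eif2s3y had base means of 4.15 and 4.24 with IL-4 in the authors' deposited table, and their list was too short to test.

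**Figure D3:**
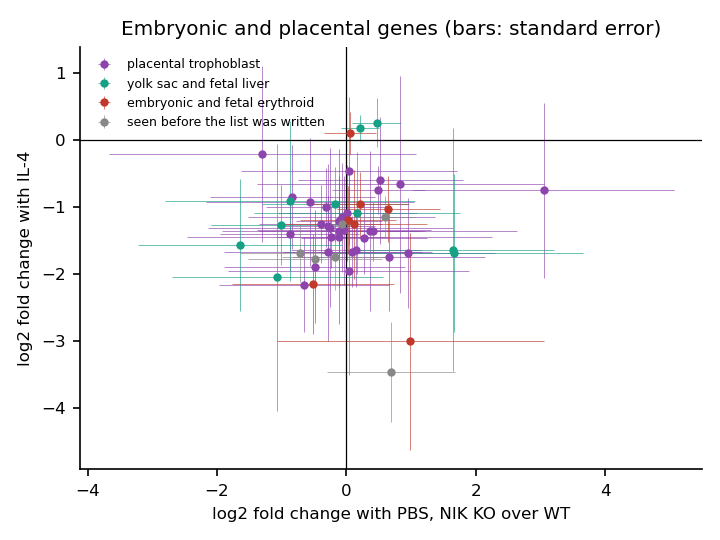
Log2 fold change, NIK KO over WT, of embryonic and placental genes measured in both tables, with PBS (horizontal) and with IL-4 (vertical). Bars are 1 standard error, colours give the list, and grey points are genes seen before the lists were written. Gdf3, also seen before, is not drawn (-1.43 with PBS and -1.56 with IL-4). With IL-4 most listed genes lie below 0 (median -1.27 over the 63 measured with IL-4, not all of them drawn). With PBS they lie on either side of it (median 0.02 over 48).

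Most IL-4 response genes stood higher with IL-4 than with PBS, a comparison of levels without a test. Arg1, the arginase of M2 macrophages, had a mean normalized count of 30.5 in WT and 17.3 in NIK KO with PBS and of 8190 and 7136 with IL-4, from the authors' deposited tables. Retnla, a secreted M2 marker, went from 2.34 and 2.67 to 1385 and 1274, and Chil3, a chitinase-like protein, from 52.3 and 64.9 to 2293 and 1699 in the authors' deposited tables. Mrc1, the mannose receptor, went from 1442 and 1544 to 24715 and 26999 (authors' deposited tables). Of 47 IL-4 response genes in both tables, 33 had a base mean at least 2-fold higher with IL-4, and 31 after the median ratio of 1.21 over 9148 genes was scaled to 1. Others differed little, such as Il4ra, Stat6 and Ppard (ratios of 1.22, 1.13 and 1.07 before scaling), and Vegfa, Il13ra1 and Il10 were lower with IL-4 (0.374, 0.675 and 0.874). Between genotypes none of Arg1, Retnla, Chil3 and Mrc1 passed with IL-4. The authors' deposited table gives Arg1 at -0.20 ± 0.15, Retnla at -0.12 ± 0.80, Mrc1 at 0.13 ± 0.18 and Chil3 at -0.43 ± 0.18 (Chil3 DESeq2 p = 0.0139, adjusted p = 1.00). The 95% intervals of Arg1, -0.50 to 0.10, and Mrc1, -0.23 to 0.48, leave out a change of 2-fold in either direction, and that of Retnla, -1.69 to 1.45, does not. With PBS the authors' deposited table gives Arg1 at -0.82 ± 0.78, Retnla at 0.19 ± 2.43, Chil3 at 0.31 ± 0.60 and Mrc1 at 0.10 ± 0.27, none called.

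**Figure D4:**
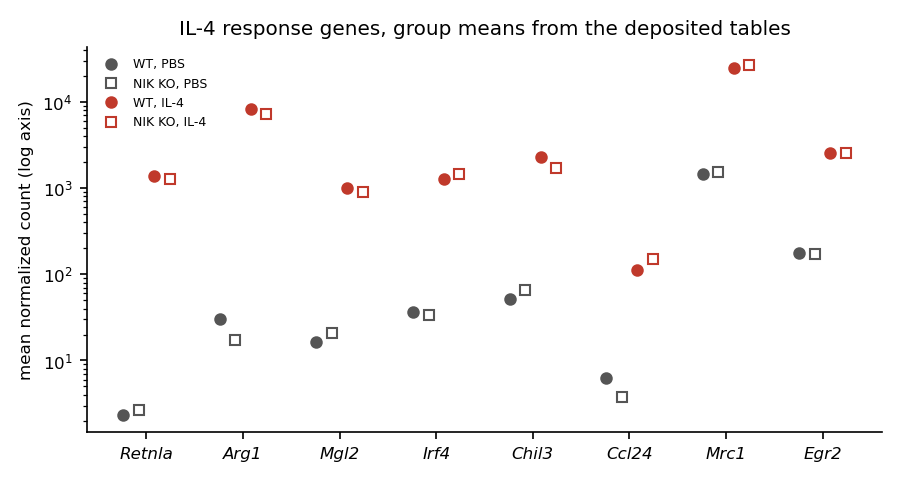
Mean normalized counts (log axis) of 8 IL-4 response genes in the 4 groups of 2 mice each, recovered from the authors' deposited tables (circles WT, squares NIK KO; grey PBS, red IL-4; no error bars, since no values per library were used). The IL-4 groups lie above the PBS groups for every gene shown, and with IL-4 the genotypes lie close together, as for Arg1 (8190 and 7136).

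The test of the difference asked whether the NIK KO effect changed with IL-4. Of 13384 genes 2 passed the z test, and both are pseudogenes with 100% of their words in another gene. They are Pgam1-ps2 and Gm10146, a copy of Lsm7 (Benjamini-Hochberg adjusted p = 0.00254 and 0.00149). Their fold changes are taken over groups listed near 0 and are no measure of size. Pgam1-ps2 went from 530 in WT to near 0 in NIK KO with PBS and from 0.180 to 144 with IL-4, and Gm10146 from 51.7 to 77.7 and from 68.4 to 0.188 (mean normalized counts from the authors' deposited tables). In all, 116 genes had an unadjusted p under 0.05. The count depends on the settings, and the test ignores that the mice are shared: 20 genes passed at an error correlation of 0.5 between the tables, and 0 passed with a t distribution or at a base mean of 100 or more. Gm45140 differed by -2.19 ± 0.51 (z test adjusted p = 0.0693), Spen, a transcriptional repressor, by 1.29 ± 0.37 (0.788) and Pappa2 by -4.15 ± 1.24 (1.00), so none of these passed. Nor did Gm10184, Dzank1, Fgd1, Gm10434 and AC154649.1, the rest of the 5 genes of smallest adjusted p in each direction. Among the gene lists, the effect on complexes II to V and on ribosomal proteins was lower with IL-4 than with PBS, by medians of -0.16 and -0.14 (cameraPR adjusted p = 0.00147 each), in a test added after the data were seen. Both were lost at an inter-gene correlation of 0.05 (adjusted p = 0.166 each). No trend on transcript length was subtracted in this test. The fifth of genes with the shortest transcripts had a median of -0.13 with IL-4 and -0.02 with PBS. Length therefore stays open as a source of these differences. Complex I did not pass (median -0.15, cameraPR adjusted p = 0.121, 0.0382 on ranks), nor did the interferon-stimulated genes (-0.08, 0.215), MHC class II (-0.13, 0.503), mitosis (0.04, 0.998), fibroblast markers (-0.45, 0.107) or IL-4 response genes (0.03, 0.998). For other fixed lists past the threshold in 1 table alone, a difference between treatments was therefore not shown.

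Agreement between the effects under both treatments was weak across all genes. Over 13384 genes, which are not independent replicates, Pearson's r of the log2 fold changes was 0.0755 and Spearman's rank correlation 0.159. Over the 9148 genes of base mean 100 or more in both tables r was 0.404 and the rank correlation 0.218, and r was 0.221 without called genes. Gm10184 was called higher and Kpna2 and Gdf3 lower in both tables, where independent calls would share 4.48e-04 higher and 0.00202 lower genes. Of the 15 genes called with IL-4 and measured in both tables, 11 had the same sign with PBS. Both tables come from the same 4 mice, so a difference between these mice that owes nothing to genotype would appear in both.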

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

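The tests of gene lists on the difference between treatments, of sequence shared between Kpna2 and its copy, of a single source of the embryonic RNA, of the size of a trend on GC content and of a trend on base mean were chosen after the result was seen, and the lists of embryonic genes were written after some of their kind had been noticed. A difference between treatments, by the test of the difference itself, marked the results given here. For Pgam1-ps2 and Gm10146 the fitted differences on the log2 scale were 34.37 and -9.10, which are no measure of size, because they rest on fold changes over groups listed near 0 (Pgam1-ps2 at 0.180 in WT with IL-4 and lower still in NIK KO with PBS, Gm10146 at 0.188 in NIK KO with IL-4). The respiratory chain list of complexes II to V differed by a median of -0.16, and the list of cytosolic ribosomal proteins by -0.14, and both calls were lost at an inter-gene correlation of 0.05 (cameraPR adjusted p = 0.166 each). Transcript length was not accounted for in the test of the difference, and short transcripts in general were lower with IL-4 than with PBS. The placental trophoblast list differed by a median of -1.24 (cameraPR adjusted p = 1.76e-10), the embryonic and fetal erythroid list by -1.38 (2.54e-05) and the yolk sac and fetal liver list by -0.52 (0.0291). The yolk sac call was lost at an inter-gene correlation of 0.05 (adjusted p = 0.0654). Genes that share 1 source of RNA move together, so the p-values of these 3 lists do not tell of the genotype.

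Kpna2 was lower and its copy Gm10184 higher in the libraries labelled NIK KO under both treatments. Counts that pass between near-identical transcripts are a candidate explanation, since 95.8% of the 31-base words of Gm10184 are in Kpna2 and the summed counts of the pair differed by 0.43 on the log2 scale with IL-4 and 0.29 with PBS. The summed signal was higher in the libraries labelled NIK KO (2140 to 2614 with PBS, 2035 to 2732 with IL-4), and lower by as much should the direction of the tables be reversed, so the sum does not tell of a loss or gain. Variants of another mouse strain carried along with the targeted gene, which could send reads from one copy to the other, stay open: Kpna2 lies 3.77 Mb from Map3k14 in the GRCm38 annotation, and genes within 10 Mb of it had larger statistics than 78.9% of random sets with PBS and 83.1% with IL-4. A true change in Kpna2, tied to genotype or to these mice, was not tested, because that needs reads.

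Embryonic and placental genes were lower in the libraries labelled NIK KO with IL-4, 58 of 63 with a median of -1.27, and not with PBS (23 of 48 lower), counts without a test because genes that share a source are not independent. RNA or reads of embryonic or placental tissue are a candidate source, with the imprinted gene Peg10 (mean normalized count 224 in WT, 134 in NIK KO) and the placental prolactin gene Prl3b1 (229 and 98.9) as the most abundant placental members measured in both tables, though 5 of the 63 genes are also in the erythroid marker list. Placental genes stood at 27.2 and 26.5 CPM in WT and NIK KO with PBS and at 115 and 47.5 with IL-4, while yolk sac and fetal liver genes in sum, held mostly by Trf, stood at 153 and 177 with PBS and at 156 and 164 with IL-4. The weighted means of the lists lay up to 5.81 standard errors apart, which would argue against one source, but that rests on 3 genes with a high level of their own with PBS (Trf, Apoc2 and Bpgm), and without them it was 0.354 (means of -1.29, -1.30 and -1.20). Whether such RNA entered before or after sequencing, or whether 1 mouse carries it, stays open without values per library, and no biological explanation was tested.

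Respiratory chain genes were lower in the libraries labelled NIK KO with IL-4 (medians -0.23 for complex I and -0.21 for complexes II to V), and so were short transcripts in general, which these genes have. Subtraction of the trend on transcript length moved the mean statistic of the lists from -0.946 to -0.650 and from -1.01 to -0.745. Both lists still passed (larger cameraPR adjusted p = 6.05e-04), and part of the effect went with length. Lengths were those of the longest annotated transcript, which need not be the one expressed. The subtraction can therefore fall short, and it does not exclude length as the whole cause. A trend on GC content was nearly flat, at a mean of -0.000987 for these genes against their mean statistic of -0.983, which argues against GC as the whole cause, while its subtraction moved too little to be a test. Subtraction of a trend on base mean moved the lists away from 0, to -1.08 and -1.25 (larger adjusted p = 3.72e-09), whereas an inter-gene correlation of 0.2 gave both an adjusted p of 0.157. RNA quality or a difference between these mice unrelated to the genotype stays open, as does an effect of the genotype, and the placental and fibroblast signal in the same libraries may go with either.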

How the results depend on the processing

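The inter-gene correlations of 0.1 and 0.2, the subtraction of trends, the removal of genes with shared words and all tests of lists on the difference were chosen after seeing the data. No paired analysis was possible because WT and NIK KO mice share no animal and the tables used hold no values per library; for that reason the removal of single libraries, a block by mouse and another normalization (TMM against DESeq2 size factors) were not run. No list that passed reversed its direction in the alternatives run, while some lists that did not pass changed direction once a trend was subtracted, such as canonical NF-κB genes with IL-4. For single genes each alternative kept the deposited fold change, so the stability of a gene's direction was not tested. A t distribution left 0 of the 17 genes called with IL-4 and 0 of the 5 with PBS (2 degrees of freedom). It left 0 of the 2 in the difference (4 degrees of freedom). Its tails are so wide that no gene could pass after adjustment, so these counts do not test the calls. With DESeq2 or the z test 418, 169 and 116 genes had an unadjusted p under 0.05. An empirical null raised the calls to 58 with IL-4 and 70 with PBS, because the statistics spread less (robust SD 0.810 and 0.641) than the test assumes. A threshold of 0.01 left 11 genes with IL-4. A base mean of at least 100 left 9 with IL-4 and 0 in the difference, and moved r between treatments from 0.0755 to 0.404. Without called genes r was 0.114 over all levels and 0.221 at that minimum, so part of the rise rests on called genes. Without genes of over 50% shared words 6 were called with IL-4 and 0 with PBS, since 8 calls with IL-4 and 4 with PBS are such genes; Gdf3 with PBS and Myo9a, Lamb3 and Col5a1 with IL-4 lost theirs once the smallest p-values had left the adjustment. An error correlation of 0.5 raised the difference to 20 genes, since it narrows the error of the difference. Of the lists, 15 with IL-4, 4 with PBS and 2 in the difference, an inter-gene correlation of 0.1 left 8, 2 and 0, and one of 0.2 left 0, 2 and 0. A correlation of 0.05 left 11 with IL-4, 4 with PBS and 0 in the difference, and one of 0 gave 4 in the difference, as the preset sets the spread that the test allows a list. Ranks gave 3 lists in the difference, complex I the added one. Fold changes in place of the statistic left 1 list with IL-4 and 0 with PBS. Unlike the statistic they are not divided by their error, so genes listed near 0 widen their spread. With PBS Pgam1-ps2 reached -24.7 and Rpl10a-ps1 24.2. A loss in this setting is therefore weak evidence against a list, and its cause was not tested. Removal of genes within 10 Mb of Map3k14 left 15 calls with IL-4 and 4 with PBS. Among named genes, counted once per treatment, 9 results gained a call under the empirical null and 9 lost one under the t distribution. Some genes count under both treatments, such as Iigp1 among the gains and Kpna2 and Gdf3 among the losses. The precision of the standard errors limits what could be seen. Among genes of base mean 100 or more, simulated changes of 1 on the log2 scale were called for 39 of 100 with PBS and 71 with IL-4. The simulated noise was wider than the spread of the real statistics.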

Other observations

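The genes and sets in this part, and the tests of these sets, were chosen after their values were seen. Genes outside the IL-4 response list also stood higher by level with IL-4 than with PBS, in the authors' deposited tables. The base mean of Il4i1, an amino acid oxidase induced by IL-4, was 76.5 with PBS and 3347 with IL-4. Pecam1, an adhesion molecule, went from 9.10 to 450, St8sia1, a sialyltransferase, from 6.99 to 397, and Aqp3, a water and glycerol channel, from 2.85 to 105 in the authors' deposited tables. On the lower side with IL-4 stood Cx3cr1, the fractalkine receptor, with 2937 and 498, and Fpr1, a receptor for formyl peptides, with 522 and 68.2. Cxcl10, a chemokine induced by interferon, went from 1380 to 317, Cebpd from 1200 to 270 and Ifit3b from 947 to 178 (authors' deposited tables). Among genes of base mean 100 or more in the higher table, 110 were at least 4-fold higher and 16 at least 4-fold lower with IL-4. These counts carry no test and were not rescaled for the median ratio of 1.21, which favours the higher side. As sets, these genes did not pass between genotypes with IL-4 (cameraPR adjusted p = 0.0623 for the higher and 0.453 for the lower set) or with PBS (0.684 and 0.307). Adjustment was over the added lists alone, which are these sets and the embryonic lists.

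Cd5l, a secreted protein of macrophages, and Fcrls, a scavenger receptor, both on chromosome 3, were not called in either of the authors' deposited tables. Cd5l was at 1.05 ± 0.29 with PBS and 0.76 ± 0.21 with IL-4, and Fcrls at 0.58 ± 0.24 and 0.64 ± 0.17 in the authors' deposited tables. Under the empirical null both passed in both tables (adjusted p = 1.05e-05 and 0.00355 for Cd5l, 0.0273 and 0.00282 for Fcrls). They were chosen after their values were seen, among 70 genes that passed this null with PBS and 58 with IL-4. AC154649.1 also passed it under both treatments, with opposite signs (-5.88 with PBS and 6.26 with IL-4), so passing in both is no support by itself.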
